A study of Zea mays with 2 samples.

How the data were processed

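Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on leaf protoplasts, cells freed of their walls, from etiolated seedlings of the maize inbred line B73. The protoplasts had been transfected with a plasmid encoding the homeodomain protein KN1 fused to a biotin ligase recognition peptide (BLRP), a short tag that a biotin ligase can biotinylate. Per the labels, 1 ChIP library and 1 input library were sequenced, so no replicate error exists for any value. Intervals and tests below cover only the counting of peaks within this pair of libraries, and neighbouring peaks are not independent.

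The submitters' processing notes name fastp 0.21.0, Bowtie2 2.4.2, SAMtools 1.11 and MACS2 without a version. The peak names hold the word rmdup and an effective genome size of 700 Mb, and the contig names and gene identifiers are those of the B73 version of the assembly called AGPv4. The deposited table has no header and gives 1 row per peak and gene. Its fold column is the authors' ratio of ChIP over input at the summit, on a linear scale. The input term is local input only where that exceeds a genome-wide floor, which set it at 91.6% of peaks. Its next columns are the authors' −log10 p-value and −log10 q-value at the summit. The deposited score equals 10 times the −log10 q-value, rounded down, in 21941 of 21965 rows. The authors also deposited the offset of the summit in bp and the distance in bp between peak edge and nearest gene, with no sign and with 0 for overlap. Peaks were called on the single ChIP library against the single input, so no pooled or replicate call is involved.

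Several limits follow from the table. Peak numbers run to 25889 while 21437 peaks are listed, so 4452 numbers (17.2%) are absent. The largest listed distance is 4998 bp, and the 147 listed peaks on contigs lie on sequences without an annotated gene. The listed peaks thus lie within 5 kb of a gene or on sequences with no gene. Whether the absent numbers are peaks farther from genes was not tested. Coordinates of peaks were converted to 1-based positions. Gene coordinates were left as given, since 114 of 114 mitochondrial genes with a locus tag have the same 1-based coordinates in the RefSeq gene table.

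Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each summit was placed upstream of, inside or downstream of its gene by strand. Of the 21168 chromosomal peaks, 89 were assigned only to RNA genes with other identifiers and were left out of the position classes. For the 330 peaks with more than 1 gene among the remaining 21079, the position was kept where the genes gave the same class, and 177 peaks with differing classes were left out, which leaves 20902. Shares have exact Clopper-Pearson 95% intervals and densities exact Poisson 95% intervals. Ratios of upstream to downstream were tested with a two-sided exact binomial test, contrasts of shares with a two-sided Fisher's exact test, and counts per chromosome with a chi-square test against chromosome extent, taken as the end of the last listed peak.

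ChIP pileup (overlapping reads after extension) and input level were solved from the deposited fold and p-value under the formulas used by MACS2, (pileup + 1) / (input + 1) and a Poisson upper tail. A whole-number pileup reproduced both values within a relative error of 1e-05 for all 21437 peaks, and the next best whole number never came closer than 0.000902. On simulated data, pileup and input were recovered for 100.0% of 21434 peaks and the position class for 100.0% of 21079 peaks. The simulation used the same formulas and 1 gene per peak. It therefore checks the computation only, not the choice of formulas or the handling of peaks with several genes. The input level was 1.85 at 19626 peaks (91.6%), the floor that MACS2 takes as the genome background, and 98.2% of the raised levels were whole multiples of 0.503 within 0.01 of a multiple. Taking the shortest peak, 229 bp (849 peaks), as the fragment length, these values correspond to an estimated 5.66 M ChIP reads after duplicate removal and 11.3 M input reads. The floor, and with it the fold at these peaks and every multiple of the background, depends on the 700 Mb in the peak names. The chromosomes extend over 2104 Mb, 3.01 times as far, and the same reads spread over that extent would average 0.616. At the 700 Mb setting the floor corresponds to 3.69 input reads per fragment length, so input differences below this floor cannot be seen in the fold values. Removing duplicates also limits the pileup to 458 start positions per fragment length on both strands. The highest pileup, 276, is 60.3% of that limit. Random sampling of positions would need 423 reads for it, so fold values of the strongest peaks are compressed by up to 1.53 times under that model.

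Before the data were examined, a motif test, gene list tests and a comparison with random positions were planned, and all of them need a genome or gene names of the same build. Neither was used here: the RefSeq gene table belongs to the later assembly Zm-B73-REFERENCE-NAM-5.0 and matched 0 of the 13947 nuclear gene identifiers. The motif and list tests were therefore not run, and positions are given as shares, the planned fallback. The rule for named genes took the 10 genes with the highest fold among peaks inside the gene or up to 2 kb from its start. Since identifiers could not be paired with symbols, only the first 2 of these are given by identifier. The kn1 and ga2ox1 genes were also to be named, and no identifier was paired with either. MicroRNA genes are named because the table itself holds their names, and mitochondrial genes because their locus tags match the RefSeq table. Both of these groups were chosen after the table had been seen, as were 2 further identifiers with high input. Alternatives were peaks above the median score, q-values under 1e-10, peak edges in place of summits, peaks with input at background, peaks with 1 gene and peaks of 400 to 600 bp.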

Results

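KN1 (KNOTTED1), a homeodomain transcription factor of the KNOX class known for its role in shoot meristems, was overexpressed with a BLRP tag in maize leaf protoplasts, and its binding was profiled by ChIP-seq. The design comprised 1 ChIP library and 1 input library, estimated from the peak statistics at 5.66 M and 11.3 M reads. The only contrast between them is the peak call, which asks where chromatin recovered with tagged KN1 exceeded input. The deposited table listed 21437 peaks, of which 21168 lay on the 10 chromosomes, 147 on 52 unplaced contigs and 122 on the mitochondrial sequence. All fold enrichments and q-values given here are the authors' own, taken at the peak summit. Without replicates, none of these values has a replicate error.

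KN1 peaks on the chromosomes were narrow and covered a wide range of enrichment. Their median width was 455 bp (quartiles 324 and 653 bp), and the widest spanned 4243 bp. The median fold enrichment over input was 9.47 (quartiles 5.96 and 18.6), and the highest was 97.1. The median ChIP pileup at a summit was 26 reads, against a background input level of 1.85, a floor that depends on the effective genome size set for peak calling. Pileups ranged from 8 to 276 reads over all peaks, so the weakest calls rest on few reads. Width and fold rose together across peaks, with a Spearman rho of 0.80, and peaks are not independent replicates. A taller pileup passes the calling threshold over a longer stretch, so part of this relation is built into the peak call.

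Of the chromosomal peaks, 21079 were assigned to 13947 annotated genes with nuclear identifiers. Of these, 9056 genes (64.9%) had 1 peak and 4891 (35.1%) had at least 2. A set of 199 genes had 5 or more, and the highest number was 10. Gene identifiers were not paired with symbols, so pathways and gene families among these genes were not analysed here.

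KN1 summits were concentrated at the starts of genes. Of 20902 peaks with an unequivocal position, 7765 (37.1%) had their summit within 500 bp of an annotated gene start. The densest 100-bp bin was the first one inside the gene, with 1653 summits, and the bin just upstream held 1457. The count fell from 865 in the second bin inside the gene to 232 in the third. No such concentration appeared at gene ends, where the densest bin held 346 summits. Among genes longer than 2000 bp, 5140 summits lay within 500 bp of a start and 1386 within 500 bp of an end, a ratio of 3.71 (95% interval 3.49 to 3.94).

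**Figure D1:**
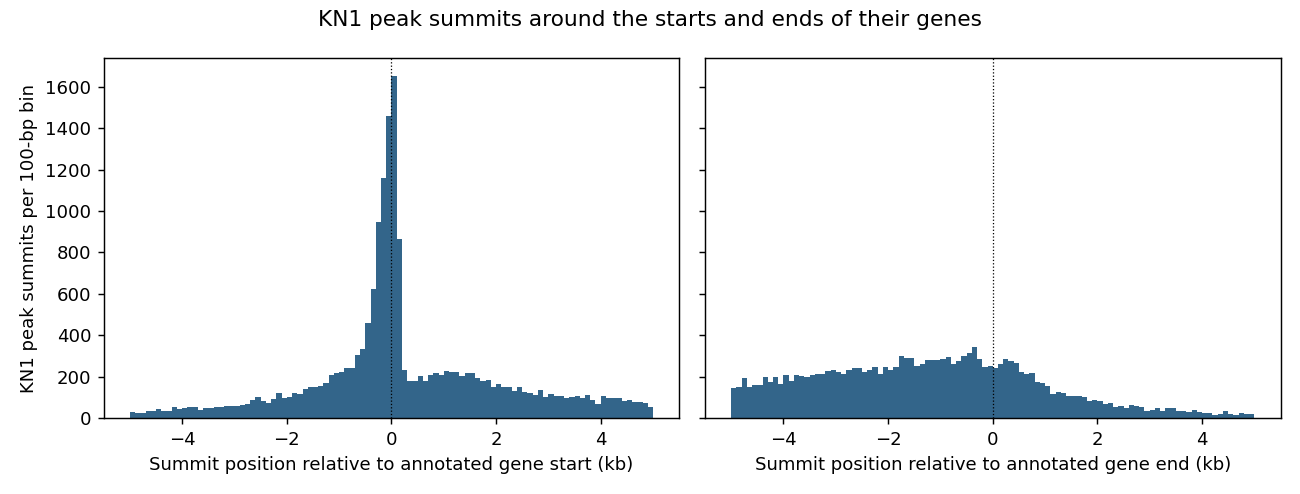
Number of KN1 peak summits per 100-bp bin (y axis) by position relative to the annotated start (left) and end (right) of the assigned gene, in kb, with negative positions before the start or end in the direction of transcription. The bin just inside the gene start holds 1653 summits, and the densest bin around gene ends holds 346.

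By class, 44.8% of summits lay upstream of their gene (95% interval 44.2 to 45.5%), 32.8% inside it (32.1 to 33.4%) and 22.4% downstream (21.8 to 23.0%). Among these peaks, which are listed only within 5 kb of a gene, the upstream summits were mostly proximal. Within 1 kb of the gene start there were 5994 peaks (28.7%), a further 1533 (7.33%) lay at 1 to 2 kb and 1847 (8.84%) beyond 2 kb. Downstream peaks numbered 2317 within 1 kb, 1112 at 1 to 2 kb and 1252 farther out. The median distance of the summit was 507 bp for upstream and 1013 bp for downstream peaks. Upstream summits outnumbered downstream ones 9374 to 4681, a ratio of 2.0 (exact binomial 95% interval 1.93 to 2.07). With peak edges in place of summits, 53.5% of peaks counted as inside a gene and 14.5% as within 1 kb upstream, because many peaks straddle the gene start.

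Inside genes, KN1 summits favoured the start. The gene end held more of the summits inside genes than the middle did, but was near an even share. The first 10% of the gene length held 2775 of 6847 such summits (40.5%, 95% interval 39.4 to 41.7%). Of the equal segments that followed, each of the third to the eighth held between 341 and 417 summits, and the last 10% held 722 (10.5%, 9.83 to 11.3%). The median gene with a summit inside was 3964 bp long.

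The strongest peaks lay outside genes more often than the weak ones. Median fold was 7.71 for summits inside genes, against 10.5 for upstream and 10.5 for downstream summits. Of the summits inside genes, 38.8% exceeded the median fold of all classified peaks, compared with 53.9% of upstream summits (Fisher's exact test, p = 3.05e-81). Among downstream summits the share was 53.4%, and the difference from upstream summits did not pass Fisher's exact test (odds ratio 0.978, p = 0.542). The share inside genes was 45.8% (43.7 to 48.0%) in the 10% of peaks with the lowest fold and 16.9% (15.3 to 18.6%) in the 10% with the highest, an odds ratio of 0.24 (Fisher's exact test, p = 1.07e-92). The odds ratio was 0.42 among peaks of 400 to 600 bp and 0.72 with peak edges in place of summits.

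**Figure D2:**
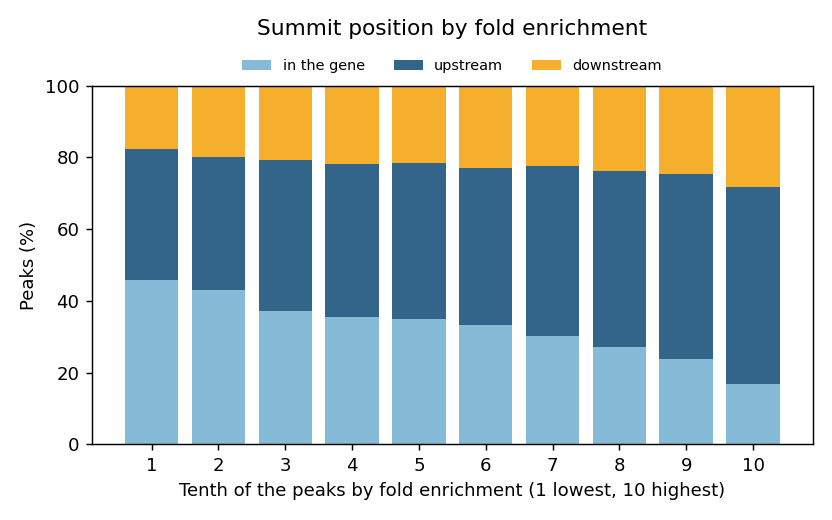
Share of peaks (%) with the summit inside, upstream of or downstream of the assigned gene, for 10 equal groups of the 20902 classified peaks ordered by fold enrichment. The share inside genes falls from 45.8% in the lowest group to 16.9% in the highest, while the upstream share rises from 36.5% to 54.8%.

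Among peaks inside a gene or up to 2 kb from its start, the highest fold was at Zm00001d026154 on chromosome 10 (139926048 to 139927942, minus strand, AGPv4). Its peak spanned 139927411 to 139928292 and overlapped the gene start, with the summit 109 bp upstream, a fold of 97.1, a pileup of 276 reads and a −log10 q of 475. The second by this rule was Zm00001d043318 on chromosome 3 (196323342 to 196324013, plus strand), whose peak at 196322032 to 196322872 had its summit 913 bp upstream and a fold of 95.001. A peak farther out, on chromosome 10 from 2349027 to 2350181 with its summit 2638 bp upstream of a gene, had a fold of 96.4. The first 10 genes by the rule all had folds of at least 85.5 and input at the genome background. In 6 of them the summit lay upstream, in 3 downstream and in 1 inside the gene. The rule shapes this split, since it admits downstream summits only within 2 kb of the gene start.

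KN1 peaks were also assigned to 35 named microRNA genes of 13 families, with 44 peaks in all. The strongest was at zma-MIR1432 on chromosome 7, where the peak at 165932579 to 165933594 had its summit 333 bp upstream of the annotated precursor and a fold of 51.9. A second peak, 2104 bp upstream, had a fold of 18.9. Next came zma-MIR396h on chromosome 9, of the family known to target growth-regulating factor genes, with folds of 40.7 and 39.3 at 1627 and 762 bp downstream. The precursor of zma-MIR396b overlaps it on the opposite strand, so the same peaks lie upstream of zma-MIR396b. Peaks assigned to the other 4 genes of the family had folds from 3.74 to 8.76. The 2 peaks upstream of zma-MIR164e on chromosome 1, of the family that targets NAC genes of organ boundaries, had folds of 34.7 and 27.7 at 2289 and 400 bp. Peaks assigned to zma-MIR164b (637 bp downstream), zma-MIR164c (551 bp upstream) and zma-MIR164d (4877 bp downstream) had folds of 3.86, 4.56 and 11.2. A peak 208 bp upstream of zma-MIR166h, whose family targets HD-ZIP III genes of leaf polarity and meristems, had a fold of 22.8. The peaks 3011 bp downstream of zma-MIR166k and 1796 bp upstream of zma-MIR166m had folds of 4.21 and 5.26.

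MicroRNA families with targets in auxin signalling were among these genes. Upstream of zma-MIR393a, of the family that targets auxin receptor genes, a peak at 289 bp had a fold of 19.3. The 2 peaks of zma-MIR393c, 2244 and 4862 bp downstream, had folds of 10.5 and 7.71. The family that includes zma-MIR167b and zma-MIR167d targets auxin response factors, and their peaks, 193 bp upstream and 1432 bp downstream, had folds of 17.9 and 8.06. Peaks assigned to zma-MIR160b (2634 bp downstream) and zma-MIR160d (580 bp upstream), also regulators of auxin response factors, had folds of 6.31 and 5.26. The family with most genes was miR156, which keeps plants in the juvenile phase by repressing SPL genes, with 8 genes, 10 peaks and folds from 4.56 to 11.9. The microRNA peaks had a median fold of 7.36, and 16 of 44 (36.4%) exceeded the median of the other chromosomal peaks, a difference from the rest that did not pass Fisher's exact test (p = 0.0987). Their summits lay upstream in 25 cases and downstream in 19. The downstream cases include the peaks of zma-MIR396b and zma-MIR396h, which lie upstream of the overlapping precursor on the other strand. The number of microRNA genes without a peak was not analysed here, so no enrichment is implied.

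Pooled over the chromosomes, listed KN1 peaks were frequent towards the ends and sparse in the middle. With each chromosome divided into 10 equal segments, the first and the last held 19.2 peaks per Mb, against 3.65 per Mb in the fourth to the sixth, a ratio of 5.26. With both ends pooled, the direction was the same on all 10 chromosomes, with ratios from 2.55 on chromosome 6 to 9.99 on chromosome 2. Taken singly, the last segment exceeded the middle on 10 chromosomes and the first on 9. The exception was chromosome 6, with 4.20 peaks per Mb in its first segment and 6.10 in its middle. An outer segment was the densest on 8 chromosomes, whereas chromosome 3 was densest in the ninth segment (19.4 per Mb) and chromosome 4 in the eighth (17.1 per Mb, against 8.87 and 10.6 at its ends). Numbers missing from the series of peak names have no listed position, and each was counted in the segment of the next listed peak on its chromosome. Counted so, they made up 11.3% of numbers at the ends and 27.3% in the middle (Fisher's exact test, p = 2.38e-93). The test treats neighbouring missing numbers as independent. Peaks in the middle also had a slightly lower median fold, 8.41 against 9.47, and 44.0% against 49.8% exceeded the chromosomal median (Fisher's exact test, p = 6.97e-07). Gene density was not analysed here, and the table is limited to the neighbourhood of genes.

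**Figure D3:**
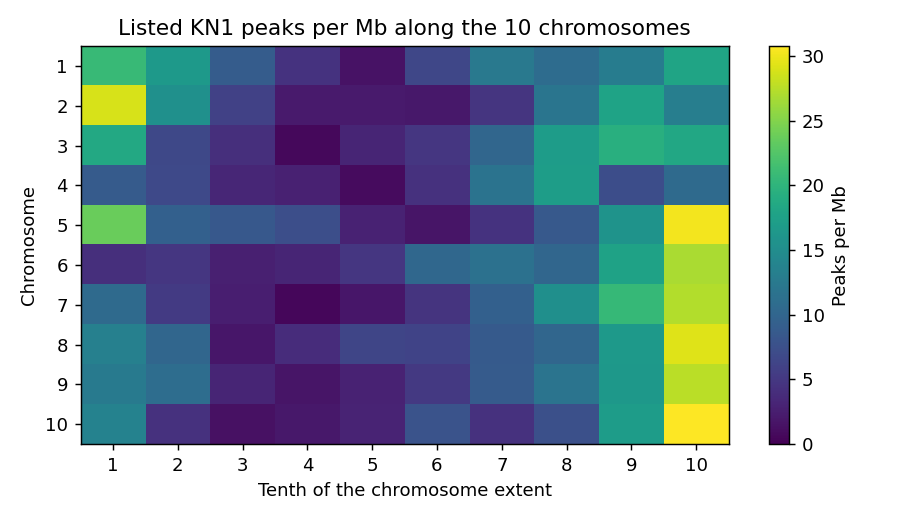
Listed KN1 peaks per Mb (colour) in each of 10 equal segments (x axis) of chromosomes 1 to 10 (y axis), with the extent of a chromosome taken to the end of its last listed peak. The outer segments average 19.2 peaks per Mb, and the fourth to the sixth 3.65.

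Between chromosomes the density varied less. Chromosome 1 had the highest, with 11.3 peaks per Mb (exact Poisson 95% interval 10.9 to 11.7), and chromosome 4 the lowest, with 7.39 (7.06 to 7.74), a ratio of 1.53. Counts departed from proportionality to extent (chi-square 281 over 10 chromosomes, p = 3.06e-55). Chromosome 4 also had the largest share of absent peak numbers, 21.6%, against 15.7% on chromosome 5.

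The mitochondrial sequence carried 122 peaks with a median fold of 5.95 (range 2.65 to 15.2), which covered 209 kb (37.2%) of the 561 kb up to the end of the last listed peak. These peaks were wider than chromosomal ones, with a median of 1036 bp. Input was raised at all of them, to a median level of 15.1, or 8.14 times the genome background, and the median ChIP pileup was 98.5 reads. Their folds are thus set against raised input, whereas the fold at 91.6% of all peaks is set against the background floor. The highest fold, 15.2, was at a peak from 77608 to 83461 inside nad4, which encodes a subunit of respiratory complex I. A peak from 267572 to 274924 over mat-r, rps1 and ccmFN had a fold of 13.98, and one from 95321 to 97341 overlapping ccmFC, a cytochrome c maturation gene, 12.6.

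**Figure D4:**
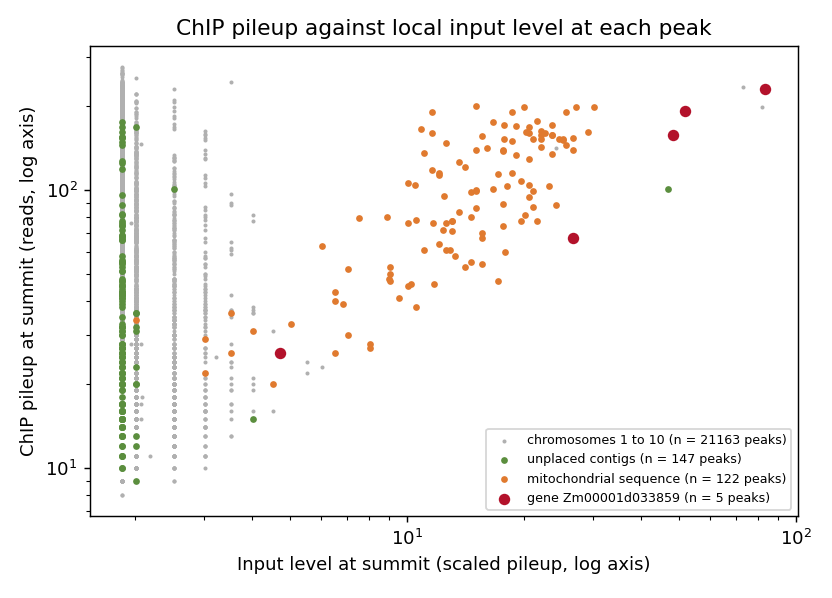
ChIP pileup at the summit of each peak against the local input level used for its fold, in reads (input scaled to the ChIP library) on log axes. Both were recovered from the deposited fold and p-value, for the chromosomes, unplaced contigs, the mitochondrial sequence and gene Zm00001d033859. The input level can come from a window wider than the summit. Mitochondrial peaks lie at a median input of 15.1, against a background of 1.85 at 91.6% of all peaks.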

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

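All tests in this part were chosen after the values had been seen. The peaks outside the chromosomes were set apart because they enter none of the position comparisons and still exceed input. Those on the mitochondrial sequence had a median fold of 5.95, and those on unplaced contigs a median fold of 9.82.

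A tagged nuclear protein would not be looked for on mitochondrial DNA. A candidate technical explanation is an even excess of mitochondrial DNA in the ChIP library over input. Under it the fold would vary by counting error alone, and the observed SD of log2 fold, 0.51, was 1.47 times the 0.35 that counting error gives. That value lies between the limits set for and against an even excess, and only called peaks are in the table, so the explanation stays open. No biological explanation was tested.

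Only 7 chromosomal peaks had an input level above 8, at 13.02 to 45.03 times the background, and the next highest level was 6.03. Of these, 4 were short peaks of 240 to 335 bp inside 1 gene of 7908 bp, Zm00001d033859 on chromosome 1 (276073335 to 276081242, minus strand), with folds of only 2.46 to 3.66 and pileups of 67 to 230 reads. A candidate explanation is DNA of the transfected KN1 plasmid, whose coding segments would map to the exons of the chromosomal gene in both libraries. It needs the gene with several such peaks to lie on the chromosome of kn1, and the RefSeq table places kn1 on chromosome 1, where the 4 peaks lie. Another peak assigned to the gene (276072238 to 276072559), 777 bp outside it, has a raised input of 4.72. That level is not a whole multiple of 0.503, so it may come from a wider window that reaches the peaks in the gene. It therefore cannot show whether input reads lie outside the gene, where a coding segment would not map. The plasmid sequence and exon positions were not used here, so the identity of the gene and the source of its input stay a hypothesis. Nuclear copies of mitochondrial DNA are also open: 5 of the 7 exceeded the highest input level at a mitochondrial summit, 30.2, but input between the mitochondrial peaks was not analysed here.

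The other 3 of these peaks lay apart. One on chromosome 5 (84633210 to 84635185) was 1976 bp wide, overlapped the start of Zm00001d015327 and had an input level of 72.9 with a fold of 3.19. One on chromosome 2 (157592793 to 157593202) had an input level of 81.9 and a fold of 2.4, and one on chromosome 10 (1982091 to 1982654) a level of 24.1 and a fold of 5.65.

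The excess of upstream over downstream summits was weighed against uneven recovery of DNA in input. Among 9126 peaks of at least 10-fold enrichment with input at the background, the ratio was 1.99 (95% interval 1.89 to 2.09), against 2.02 among all peaks of at least 10-fold. Only 740 of those had raised input, so the ratio would have been 1.72 even if all 740 lay upstream. The comparison could hardly have come out otherwise, and uneven input stays open. Recovery of open chromatin without KN1 binding is likewise untested, since no ChIP library without tagged KN1 was analysed here.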

How the results depend on the processing

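The upstream excess kept its direction and significance under all the alternatives run, with ratios from 1.49 (peak edges) to 2.12 (peaks of 400 to 600 bp), and so did the lower share inside genes among strong peaks. Variation between chromosomes was recomputed only above the median score, where it held (ratio 1.58). The share of summits within 1 kb upstream, 28.7%, became 30.8% among peaks above the median score, 30.1% at q under 1e-10, 29.8% among peaks of 400 to 600 bp and 14.5% with peak edges. The share inside genes, 32.8%, became 26.1% above the median score, 28.7% at q under 1e-10 and 53.5% with peak edges. Edges change the classes by construction, since any overlap counts as inside. The ratio of chromosome ends to middle, 5.26, was 5.97 above the median score, a setting added after seeing the data. The score and q-value shifts are not separate from the fold differences given above, since score and fold both rise with pileup at background input. The cause of those differences and of the width shift was not tested. Limiting peaks to background input or to 1 gene, both chosen after seeing the data as was the width limit, where run, moved none of these values beyond its interval. Random placements, gene-number scaling and all motif and gene list settings were not run, because no genome or annotation of this build was used. No replicate could be left out with 1 library per group. No paired analysis was possible because each group has 1 library. Depth limits the weakest calls, at 8 reads, and depth and the effective genome size together set the floor of 3.69 reads per fragment length, below which input differences are hidden.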

Other observations

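Beyond the families described above, single peaks lay near microRNA genes of other families. A peak 468 bp upstream of zma-MIR528a had a fold of 17.9 and one 350 bp upstream of zma-MIR528b a fold of 4.91. Upstream of zma-MIR171i, of the family that targets GRAS genes of the HAM group, a peak at 768 bp had a fold of 17.2, and one 3357 bp upstream of zma-MIR171l a fold of 6.66. A peak 561 bp upstream of zma-MIR159f, whose family targets GAMYB genes of the gibberellin response, had a fold of 10.2. Those 3978 bp upstream of zma-MIR169c and 1261 bp upstream of zma-MIR169l, regulators of NF-YA genes, had folds of 6.66 and 7.01. The peak assigned to zma-MIR482 had its summit 148 bp downstream and a fold of 8.76.

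Unplaced contigs held 147 peaks on 52 sequences with a highest fold of 61.7. One of them, from 52495 to 52947, had an input level of 46.7 and a fold of 2.14, the lowest in the table.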
